A study of Homo sapiens and Mus musculus with 28 samples.

How the data were processed

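RNA-seq profiles of 28 libraries in 8 groups were analysed: 12 from mouse (naive T cells and Th9 cultures at d3, d4 and d8, with 3 numbered sets each) and 16 from human (naive T cells and Th9 cultures at d5, d8 and d15, with 4 donors each). The same 4 donors recur at every time by their labels, while the labels give the mouse replicates only as set numbers. Libraries were made with the NEBNext Ultra II Directional kit, per the labels. Per the submitters' processing notes the data went through bcl2fastq 2.20.0.422, cutadapt 1.18, STAR, RSEM and DESeq2, against the builds mm10 for mouse and GRCh38 or hg38 for human, without a statement of what each tool did. The authors deposited 1 table of FPKM per species, and the values behave as FPKM as estimated by RSEM: no negative value, no common sum, and no log scale. Deposited FPKM were used as they stand, since counts were not part of the tables, and DESeq2 results of the submitters were not used here.

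The tables list 55450 mouse and 58870 human genes. Of the human entries, 45 second copies of pseudoautosomal genes were left out. Names that occur for more than 1 entry numbered 110 in mouse and 149 in human, and the entry with the highest mean was taken for a named gene. Genes entered the test when FPKM reached 1 in at least 3 mouse or 4 human libraries, which left 13008 mouse and 14147 human genes. Correlations of log2 values within a group lay between 0.935 and 0.982 in mouse and between 0.900 and 0.983 in human, and 0 mouse libraries correlated better with another group than with their own. Absolute depth cannot be read from FPKM. Relative depth was estimated from the commonest ratio of FPKM between each pair of libraries, over genes above 0 in few libraries, where a value often stands for a single read, and it differed by a factor of up to 1.81 among mouse and 1.84 among human libraries.

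The model was limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with 1 mean per group, all 4 groups of a species in the same fit, moderated variances with a trend on the mean, equal weights and no term for set or donor. A gene was called when its p-value, adjusted by Benjamini and Hochberg over all tested genes of the comparison, was under 0.05. Each species had 5 comparisons: end of stimulation against naive, each later time against the time before, end of culture against end of stimulation, and end of culture against naive. Mouse and human were never tested against each other, because each species has its own table, protocol and times. They were set side by side by gene symbol, as counts of calls in the same and in opposite directions beside the counts for independent lists. The same was done for genes that rose at the end of stimulation and fell by the end of culture, and again with the libraries at the end of stimulation divided between the 2 comparisons. The mouse division was added after the data were seen, and it leaves 1 comparison with a single d3 library, which is assumed to vary like the other groups. Python 3.11.15 and matplotlib 3.10.9 made tables and figures.

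The groups, comparisons, gene lists, rule for naming genes and alternatives were chosen before the data were examined, except where the text says otherwise. Genes are named by 3 rules. The first takes 16 core genes, of which 1 is not reported here and the others are Il9, Il4, Il5, Il13, Il10, Irf4, Batf, Spi1, Gata3, Il1rl1, Il2ra, Cish, Ccr7, Tcf7 and Mki67, with their human counterparts. The second takes, per comparison, the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 FPKM in the higher group and no overlap between the groups' libraries, without antigen receptor segments and sex-linked marker genes. The pattern that finds the segments was corrected after the data were seen, since it had missed Tcrg-C2. The third takes, per gene list and comparison, the 2 called members that rose most and the 2 that fell most. Further members of a list are named where they did not pass or were not tested.

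The 27 lists were Th9 and type 2 cytokines, Th9 transcription factors, IL-2 and STAT5 responsive genes, Th1, Th2, Th17, Treg and Tfh genes, TGF-β responsive genes, alarmin and innate cytokine receptors, cytotoxic genes, chemokine receptors and homing, naive and quiescence genes, immediate early and TCR-induced genes, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis and amino acid stress genes, interferon response genes, p53 response genes, and markers of B cells, myeloid cells, CD8 T and NK cells, red cells and platelets, and mast cells and basophils. List results are counts of called members, with no test of the list as a set. Counts were also taken with p-values adjusted over the tested members of the list alone.

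Alternatives changed 1 choice at a time: a pseudocount of 0.1, no filter on low values, TPM, median-of-ratios or quantile scaling, no variance trend, only the 2 groups compared in the fit, array quality weights, a change of at least 2-fold for a call, the set or donor as a block, and each library left out in turn. Alternatives added after seeing the data were leaving out mouse set 1, and using only human donors 1 and 2 or only donors 3 and 4. Group means of at least 5 FPKM given in the text were also taken without each library in turn, a step added after the data were seen. Every comparison was also run on all splits of its libraries into groups of the same size, 10 in mouse and 35 in human with the real grouping included. The fit was tested on simulated data with known changes in 200 genes, made from the naive means and the spread of each gene. It called 52.2% of 2-fold and 97.0% of 4-fold changes from mouse values with 3 libraries per group, and 49.3% and 93.9% from human values with 4. Unchanged genes that were called numbered 11 in mouse and 4 in human. Changes were made only in genes above a minimum naive level, so the rates do not cover genes near the filter. With so few changed genes the adjustment of p-values is stricter than in the real comparisons, so these rates need not hold there. Mouse d3 against naive had 8350 calls, of which 5294 were at least 2-fold.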

Results

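Th9 cells are CD4 helper T cells that secrete interleukin-9 (IL-9), and they can be grown from naive CD4 T cells with IL-4 and TGF-β. Transcriptomes of naive T cells and of cells at 3 later days of a Th9 culture were measured by RNA-seq in mouse and in human. The mouse data held 12 libraries, with 3 numbered sets at day 0 (naive), 3, 4 and 8. The human data held 16 libraries, with 4 donors at day 0 (naive), 5, 8 and 15. Mouse naive CD4 cells from spleen and lymph nodes of C57BL/6 mice, an inbred strain, were stimulated through CD3 and CD28 for 3 days with IL-4 at 20 ng/mL, IL-2 at 10 ng/mL and TGF-β at 5 ng/mL. IFN-γ was blocked. They were then washed and kept with the cytokines but without the stimulating antibodies, so that d4 lay 1 day and d8 lay 5 days past stimulation. Human naive CD4 cells from blood had 5 days of stimulation with IL-4 at 30 ng/mL, the same IL-2 and TGF-β doses and IL-1β at 10 ng/mL. Their d8 and d15 lay 3 and 10 days past its end. The d15 protocol text leaves out the plate-bound anti-CD3 antibody that is named for d5 and d8. Comparisons with d15 below take this as an omission from the text. The labels of 1 human naive library name the mouse strain, and it was taken as human because its column stands in the human table. The values were FPKM, and the depth in reads was unknown. The commonest ratio between libraries in genes of low level gave relative depths from 0.743 to 1.35 among the mouse libraries and from 0.739 to 1.36 among the human libraries, where 1 is the typical library of the species.

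The groups stood apart in a principal component analysis of log2 values. The first component held 56.4% of the variance in mouse and 55.6% in human, and the second held 20.6% and 15.0%. The third human component, with 9.79%, parted donors 1 and 2 from donors 3 and 4 within every group. Totals of calls within each pair of donors are therefore given beside the total of each human comparison. Levels below are mean FPKM ± SD (n = 3 sets in mouse and n = 4 donors in human), and log2 changes are on the scale of log2(FPKM + 1) with their standard error. Labels do not say whether the mouse sets came from separate animals, so mouse p-values measure the spread between these sets. A count of list members adjusted over the list alone equalled the count adjusted over all tested genes unless it is given in brackets. Leaving out 1 library moved 22 of 122 mouse means and 8 of 114 human means of at least 5 FPKM by over 1.5 times, and set 1 was the library in 19 of the 22. Their values are given in the paragraphs below.

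**Figure D1:**
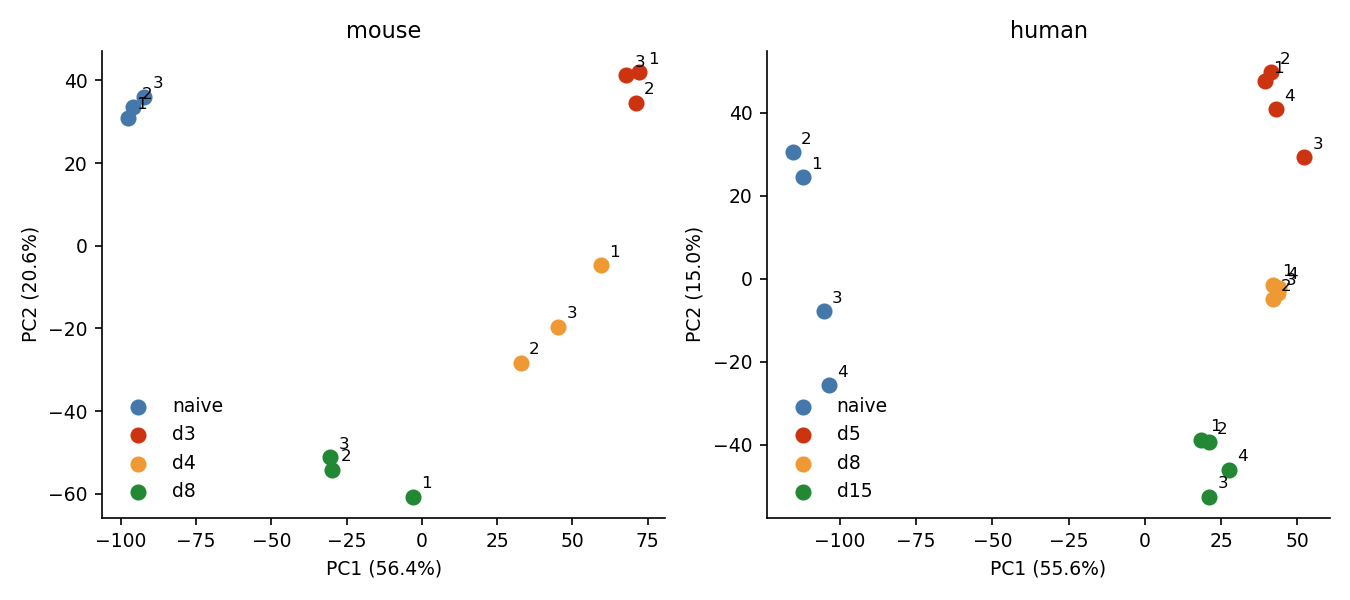
Principal component scores (first component on the horizontal axis, second on the vertical axis, without units, with the share of variance on each axis) of the 12 mouse libraries (left) and the 16 human libraries (right), with 1 point per library, coloured by day and numbered by set or donor. Naive libraries lie apart from the stimulated groups on the first component, which held 56.4% of the variance in mouse and 55.6% in human.

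Mouse d3 cells, after 3 days of stimulation under Th9 conditions, were compared with uncultured naive cells. No group parts stimulation from the cytokines or from culture itself, in either species. Il9 (ENSMUSG00000021538.3), the cytokine that names these cells, rose from 0.67 ± 0.052 to 756 ± 320.2 FPKM (log2 change 8.71 ± 1.26 SE, limma adjusted p = 9.26e-05). Il2ra (ENSMUSG00000026770.5), the α chain of the IL-2 receptor, rose from 1.01 ± 0.167 to 321 ± 57 (log2 change 7.31 ± 0.19 SE, limma adjusted p = 5.54e-10). Also among the largest rises was that of Scd1, a fatty acid desaturase, from 0.237 ± 0.179 to 160.2 ± 12.4. The chemokine receptor Ccr8 rose from 0.37 ± 0.121 to 189 ± 91.1 and Crabp2, a carrier of retinoic acid, from 0.413 ± 0.415 to 179.7 ± 40.8. The largest falls included that of Ly6c1, a surface protein of naive and memory T cells, from 173 ± 18.4 to 0.0167 ± 0.0289. Rasgrp2, an activator of the small GTPase Rap1, fell from 481 ± 26.9 to 3.27 ± 1.57, and the interferon-inducible gene Ifi213 from 114 ± 13.9 to 0.0633 ± 0.0231.

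Among the Th9 and type 2 cytokines, 9 of 12 tested members rose and 0 fell at d3. Il13 rose from 0.0200 ± 0.0346 to 23 ± 28.3 and the chemokine Ccl17 from 0 to 32.3 ± 16.8. Il4 rose from 0 in every naive library to 6.52 ± 4.52. Of the Th9 transcription factors, 10 of 20 tested members rose and 6 fell (11 and 6 adjusted over the list alone). Bhlhe40 rose from 0.463 ± 0.255 to 151 ± 12.7 and Irf4, which Th9 differentiation requires, from 1.32 ± 0.502 to 150.2 ± 10.2. Batf3 rose from 0.0867 ± 0.085 to 86.3 ± 49.5 and Batf from 33.9 ± 5.21 to 99.2 ± 14.9. Ets1 fell from 398 ± 50.8 to 93.8 ± 12.1. Spi1, which encodes PU.1, lay at 0.0933 ± 0.0862 in naive cells and 0.0900 ± 0.0781 at d3, under the filter on low values. Il5 at 2.78 ± 4.05 at d3 was also not tested. Genes of other helper lineages moved too. All 5 tested Th17 genes rose, with Il17f going from 0.200 ± 0.115 to 65 ± 53.2 and Ccr6, the homing receptor of Th17 cells, from 0.0167 ± 0.0289 to 90.8 ± 47.7. Of the Treg genes, 5 of 7 rose, among them the checkpoint receptor Ctla4 from 3.44 ± 1.11 to 148 ± 59.1. Of the Tfh genes, 3 of 5 tested members rose and 1 fell, with Pdcd1, another checkpoint receptor, going from 2.15 ± 0.324 to 57.4 ± 11.9. Of the immediate early and TCR-induced genes, 7 of 19 tested members rose and 8 fell. In that list the costimulatory receptors Tnfrsf9 from 2.92 ± 0.862 to 273 ± 108 and Tnfrsf4 from 7.97 ± 0.451 to 426 ± 77.8 rose. Fos fell from 136 ± 38.8 to 6.61 ± 3.52. Without set 1 the d3 means were 6.78 for Il13, 35.5 for Il17f and 4.1 for Il4.

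Growth and metabolism genes rose together at d3. All 22 cell cycle genes were higher, with the mitotic kinase gene Cdk1 going from 0.637 ± 0.509 to 163 ± 39.1 and Mki67, the proliferation marker Ki-67, from 0.597 ± 0.334 to 89.4 ± 18.9. So were 15 of 16 glycolysis genes (Tpi1, triosephosphate isomerase, from 21.5 ± 0.399 to 1187 ± 333) and 16 of 18 cholesterol synthesis genes (Cyp51 from 12.3 ± 3.18 to 149.7 ± 78.4). Higher too were 14 of 15 genes of oxidative phosphorylation (Ndufb8 from 58 ± 5.00 to 254 ± 14.9) and 11 of 16 of ribosome biogenesis (Ncl from 244 ± 9.45 to 958 ± 90.0). The same held for 11 of 14 of the amino acid stress list (Asns, asparagine synthetase, from 0.453 ± 0.163 to 89.7 ± 41.9). In contrast, 18 of 20 naive and quiescence genes fell, including Klf2, the factor that maintains quiescence and homing, from 167 ± 21.7 to 4.32 ± 1.75 and Tcf7, which encodes TCF-1, from 609 ± 104 to 40.5 ± 12.6. All 15 interferon response genes fell, with the interferon regulator Irf7 going from 53.4 ± 2.28 to 0.743 ± 0.933. Limma called 4248 higher and 4102 lower of 13008 tested genes at d3. The median log2 change of all tested genes was 0.02 as deposited and -0.12 with each library scaled to a common sum (TPM). The share of calls that were higher was 50.9% as deposited, 49.6% without a filter on low values, 48.1% with quantile normalization and 44.6% with TPM scaling.

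From mouse d3 to d4, the first day without stimulation, immediate early and TCR-induced genes were among those that fell. Of this list, 13 of 19 (15 adjusted over the list alone) fell and 0 rose, with the orphan nuclear receptors Nr4a3 going from 50.4 ± 7.27 to 2.43 ± 2.5 FPKM (log2 change -4.13 ± 0.39 SE, limma adjusted p = 0.000101) and Nr4a1 from 52.8 ± 10.9 to 5.56 ± 3.74. Of the IL-2 and STAT5 responsive genes, 3 of 15 tested members rose and 4 fell, Lta, lymphotoxin α, going from 381 ± 178 to 61.4 ± 31.2. Cd200, an inhibitory surface protein, fell from 169 ± 8.34 to 17.4 ± 5.12. Crabp2 fell from 179.7 ± 40.8 to 2.94 ± 1.05 and Ccr6 from 90.8 ± 47.7 to 8.35 ± 1.83. Of the Th9 and type 2 cytokines, 1 of 12 tested members rose and 7 fell (2 and 8 adjusted over the list alone). Il9 was at 756 ± 320.2 at d3 and 174 ± 192 at d4, which did not pass the test (log2 change -3.31 ± 1.26 SE, limma adjusted p = 0.0858). Its d4 level was 384 in set 1, 5.84 in set 2 and 132.5 in set 3. Without the d4 library of set 1 it passed (log2 change -4.54, limma adjusted p = 0.0194). The d4 mean of Nr4a1 was 3.43 without set 1.

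Genes that rose by d4 included Smtn, a smooth muscle cytoskeletal gene, from 2.14 ± 0.38 to 79.7 ± 61.9 (log2 change 4.37 ± 0.47 SE, limma adjusted p = 0.000202), and Il17rb, a chain of the IL-25 receptor, from 0.38 ± 0.16 to 19.9 ± 6.92. Tnfsf13b, which encodes the B cell factor BAFF, rose from 2.25 ± 0.713 to 44.4 ± 19.8, and the guanylate binding protein gene Gbp4 from 0.527 ± 0.281 to 19.8 ± 11. Il4ra, a chain of the IL-4 receptor, rose from 66.4 ± 20.7 to 234 ± 23.2. Of the TGF-β responsive genes, 6 of 12 (8 adjusted over the list alone) rose. Itgae, the αE integrin CD103, went from 0.397 ± 0.106 to 8.57 ± 6.36 and Ldlrad4, an inhibitor of TGF-β signalling, from 8.17 ± 1.28 to 46 ± 7.09. Of the naive and quiescence genes, 9 of 20 tested members rose and 1 fell, with Klf2 going from 4.32 ± 1.75 to 31.2 ± 16.5. S1pr1, which lets T cells leave lymph nodes, rose from 9.05 ± 5.05 to 42.6 ± 9.07. None of the 22 cell cycle genes passed the test, and Mki67 was at 147 ± 61. The test called 1613 higher and 980 lower genes. The total of 2593 was 1690 without the d3 library of set 2, 1431 without the d4 library of set 2, 1375 without the d4 library of set 3 and 4861 without set 1, a choice made after seeing the data. The share of calls that were higher was 62.2% as deposited (median log2 change of all genes 0.07), 82% with TPM scaling (0.24) and 51.9% with median-of-ratios scaling (0.01). Without set 2 the d4 means were 45.6 for Smtn and 4.91 for Itgae.

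**Figure D2:**
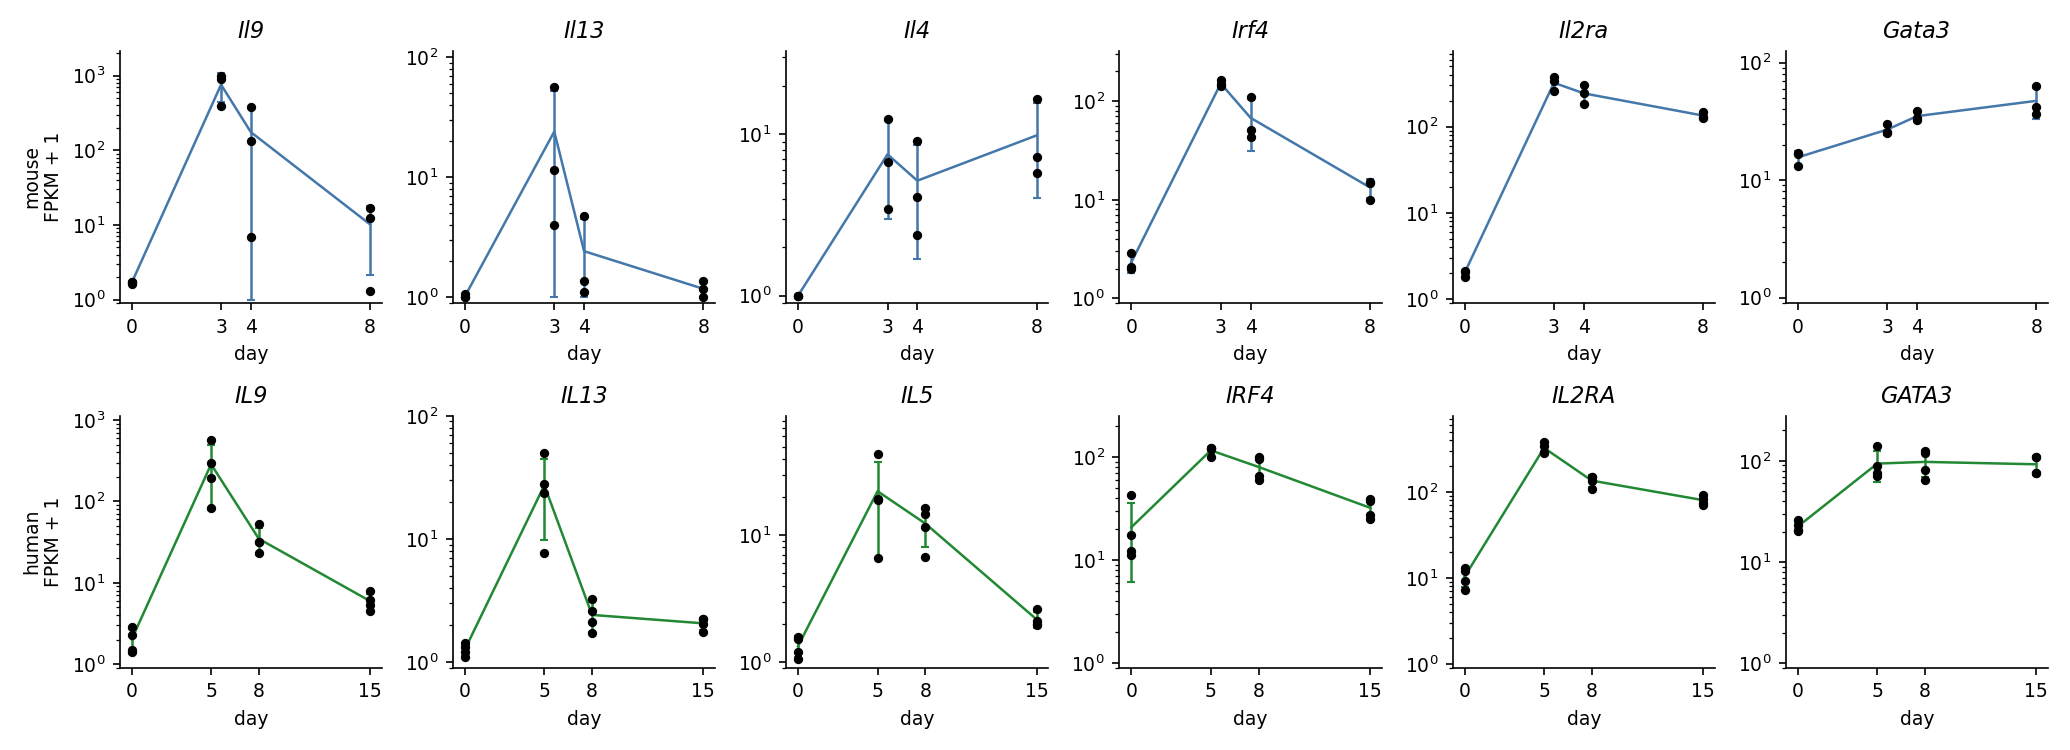
Expression of cytokine, receptor and regulator genes in FPKM (vertical axis, log scale, with a pseudocount of 1 added) against day of culture (horizontal axis) for 6 mouse genes (top) and 6 human genes (bottom), with 1 point per library, a line through the group means and bars of 1 SD that stop at 0 FPKM. Il9 went from 0.67 in naive mouse cells to 756 at d3 and 9.16 at d8, and IL9 from 1.01 in naive human cells to 285 at d5 and 4.96 at d15.

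Between mouse d4 and d8, 4 further days without stimulation, genes of the cell cycle list and of 4 metabolic lists fell. All 22 cell cycle genes fell, with Mki67 going from 147 ± 61 to 33 ± 17.8 FPKM (log2 change -2.14 ± 0.38 SE, limma adjusted p = 0.00191). Falls took in 14 of 18 (17 adjusted over the list alone) cholesterol synthesis genes (Fdps, farnesyl diphosphate synthase, from 170.2 ± 47.6 to 32.4 ± 14.9) and 11 of 15 (13 adjusted over the list alone) oxidative phosphorylation genes (Atp5b from 1494 ± 309 to 649.8 ± 102). They also took in 10 of 16 (11 adjusted over the list alone) glycolysis genes (Pgk1 from 974 ± 182 to 226 ± 50.1) and 7 of 14 amino acid stress genes (Phgdh, a serine synthesis enzyme, from 281 ± 68.6 to 60.2 ± 11.4). Scd1 fell from 158 ± 13.7 to 5.41 ± 1.16 and Stra6, the receptor for retinol binding protein, from 21.6 ± 21.4 to 0.15 ± 0.0693. Bcat1, a branched-chain aminotransferase, fell from 24.2 ± 8.79 to 0.987 ± 0.618 and Irf4 from 66.8 ± 36.3 to 12.4 ± 2.95. Without set 1 the d4 mean of Stra6 was 9.22.

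Gzma, the cytotoxic protease granzyme A, rose from 0.833 ± 0.994 to 668 ± 1077 (log2 change 6.35 ± 1.22 SE, limma adjusted p = 0.00273). The other largest rises were those of Ly6a, the Sca-1 antigen, from 6.07 ± 7.62 to 365 ± 496 and Itgae from 8.57 ± 6.36 to 269.6 ± 217, of the chemokine receptor Cxcr6 from 6.7 ± 3.03 to 192 ± 92.4, and of Acat3, an acetyl-CoA acetyltransferase gene with a near copy, from 0.600 ± 0.291 to 126 ± 22.1. Of the cytotoxic genes, 4 of 9 tested members rose and 1 fell (6 and 1 adjusted over the list alone), and of the chemokine receptor and homing genes 4 of 14 tested members rose and 2 fell (5 and 3 adjusted over the list alone). Gzma lay at 1911 in set 1, 76.2 in set 2 and 16.4 in set 3 at d8. Il1rl1, which encodes the IL-33 receptor ST2, rose from 0.173 ± 0.00577 to 14.2 ± 13 (log2 change 3.35 ± 0.43 SE, limma adjusted p = 0.000336), and Il7r, the α chain of the IL-7 receptor, from 24.6 ± 9.75 to 220.0 ± 129. Hpgds, a prostaglandin D synthase of Th2 cells, rose from 4.03 ± 1.16 to 37.9 ± 7.49, and Entpd1, the ATP-degrading enzyme CD39, from 9.91 ± 2.99 to 58 ± 12.2. Il9 was at 174 ± 192 at d4 and 9.16 ± 7.99 at d8 and did not pass (log2 change -3.45 ± 1.26 SE, limma adjusted p = 0.0515). It passed with median-of-ratios scaling (-3.52, limma adjusted p = 0.0481), with quantile normalization (0.0485) and without the d4 library of set 2 (-5.13, adjusted p = 0.00241). Limma called 2626 higher and 2064 lower genes. The total of 4690 was 2973 without the d8 library of set 2. The median log2 change of all genes was 0.07 as deposited and 0.18 with TPM scaling. The share of calls that were higher was 56% as deposited, 65.4% with TPM scaling, 47.7% with median-of-ratios scaling and 49.7% with quantile normalization. Without set 1 the d8 means were 46.3 for Gzma, 79.1 for Ly6a, 145.7 for Itgae, 6.7 for Il1rl1 and 145.5 for Il7r, and the d4 means were 1.67 for Ly6a and 69.2 for Il9. Without set 3 the d8 mean of Il9 was 5.81.

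Over the whole span from the end of stimulation, mouse d8 against d3, Il9 fell from 756 ± 320.2 to 9.16 ± 7.99 FPKM (log2 change -6.76 ± 1.26 SE, limma adjusted p = 0.000832). Il10, an anti-inflammatory cytokine, rose (log2 change 3.52 ± 0.53 SE, limma adjusted p = 0.00021). Il13 fell from 23 ± 28.3 to 0.18 ± 0.185, whereas Il24 rose from 2.84 ± 1.25 to 19.7 ± 3.06. In all, 3 of 12 tested members rose and 8 fell in that list. Of the immediate early and TCR-induced genes, 12 of 19 fell. Of the Th17 genes, 1 of 5 tested members rose and 4 fell, with Il17f going from 65 ± 53.2 to 1.28 ± 1.25. Crabp2 fell from 179.7 ± 40.8 to 0.0733 ± 0.0643 and Dapl1 from 134 ± 86.5 to 0.47 ± 0.200. Lad1, a gene of basement membrane anchoring filaments, fell from 88.1 ± 57.6 to 0.0900 ± 0.0693 and Cd200 from 169 ± 8.34 to 1.63 ± 0.601. Rises were led by Itgae from 0.397 ± 0.106 to 269.6 ± 217 (log2 change 7.30 ± 0.50 SE, limma adjusted p = 1.5e-06) and Gzma from 0.0600 ± 0.0100 to 668 ± 1077. Ecm1, extracellular matrix protein 1, rose from 3.16 ± 0.974 to 592 ± 582 and Ly6a from 0.917 ± 0.405 to 365 ± 496. Lrrc32, the carrier of latent TGF-β named GARP, rose from 2.59 ± 1.94 to 109 ± 25.4, within a Treg list of which 5 higher and 1 lower of 7 passed. Naive and quiescence genes rose from their d3 levels, with 15 higher and 1 lower of 20 (16 and 1 adjusted over the list alone). The return was partial, since d8 against naive cells had 1 higher and 9 lower of this list (median log2 change -0.76). Klf2 rose from 4.32 ± 1.75 to 114 ± 51.6, Il7r from 8.82 ± 7.1 to 220.0 ± 129 and Tcf7 from 40.5 ± 12.6 to 161 ± 53.1. The falls held 21 of 22 cell cycle, 17 of 18 cholesterol synthesis, 13 of 16 glycolysis and 13 of 16 (15 adjusted over the list alone) ribosome biogenesis genes. Npm1, nucleophosmin, fell from 2295 ± 469 to 609 ± 124. Genes called by limma numbered 4398 higher and 3212 lower, of which 57.8% were higher (71.8% with TPM scaling and 49.6% with median-of-ratios scaling). The median log2 change of all genes was 0.13 as deposited, 0.40 with TPM scaling and -0.01 with median-of-ratios scaling. Without set 1 the d8 mean of Ecm1 was 255.9, and the d3 means were 86 for Dapl1, 54.8 for Lad1 and 4.72 for Il7r.

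Mouse d8 cells, set against naive cells, had higher levels of Treg, Th2 and TGF-β responsive genes, with the counts given below. Lgals3, the lectin galectin-3, rose from 0.413 ± 0.286 to 805 ± 204 FPKM (log2 change 9.14 ± 0.41 SE, limma adjusted p = 4.81e-08), Cxcr6 from 0.437 ± 0.16 to 192 ± 92.4 and Il2ra from 1.01 ± 0.167 to 133 ± 13. All 7 tested Treg genes rose, including Foxp3, the Treg lineage factor, from 1.03 ± 0.694 to 61.4 ± 7.53 (log2 change 4.98 ± 0.66 SE, limma adjusted p = 0.000134). Lrrc32 rose from 0.0833 ± 0.0404 to 109 ± 25.4 and Entpd1 from 0.677 ± 0.933 to 58 ± 12.2. Of the Th2 genes, 7 of 8 rose. Gata3, the Th2 lineage factor, went from 14.6 ± 2.14 to 46.3 ± 14, Ccr4 from 0.283 ± 0.0764 to 40.6 ± 32.8 and Il4 from 0 to 8.85 ± 5.82. Of the IL-2 and STAT5 responsive genes, 10 of 15 tested members rose and 1 fell (11 and 1 adjusted over the list alone). Socs2, a feedback inhibitor of cytokine signalling, rose from 0.36 ± 0.0872 to 119 ± 10.4 and Cish, another, from 8.55 ± 1.05 to 232 ± 70.0. Of the TGF-β responsive genes, 9 of 12 rose. Of the p53 response genes, 7 of 13 tested members rose and 1 fell (8 and 1 adjusted over the list alone), Cdkn1a, the cell cycle inhibitor p21, going from 0.22 ± 0.0800 to 48.2 ± 18.8. Il9 was 0.67 ± 0.052 in naive cells and 9.16 ± 7.99 at d8 and did not pass (log2 change 1.96 ± 1.26 SE, limma adjusted p = 0.262). Its d8 level was 0.31 in set 1, 11.3 in set 2 and 15.86 in set 3. Without the d8 library of set 1 the log2 change was 3.11 (limma adjusted p = 0.0872), and with array quality weights it passed (2.87, limma adjusted p = 0.000421). Lower than in naive cells were Dapl1 from 201 ± 16.3 to 0.47 ± 0.200 and Ly6c1 from 173 ± 18.4 to 0.293 ± 0.389. Dtx1, a regulator of Notch signalling, fell from 74.7 ± 9.62 to 0.167 ± 0.0764. So did 14 of 15 interferon response genes, Isg15 going from 23.3 ± 2.35 to 1.81 ± 2.7. There were 2833 higher and 1501 lower calls. The share higher was 65.4% as deposited (median log2 change of all genes 0.12), 49.4% with median-of-ratios scaling (-0.01), 47.9% with quantile normalization (-0.05) and 75.9% with TPM scaling (0.25). Without set 1 the d8 means were 21.7 for Ccr4 and 5.52 for Il4.

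The matching human comparison, d5 against naive, covers 5 days of stimulation with IL-1β among the cytokines. IL9 rose from 1.01 ± 0.698 to 285 ± 207 FPKM (log2 change 6.89 ± 0.44 SE, limma adjusted p = 1.13e-09). The gene lies on the minus strand of chromosome 5, from 135892246 to 135895827 of GRCh38, in GENCODE release 29. ZBED2, a zinc finger transcription factor gene, rose from 1.21 ± 0.611 to 261 ± 55.4 (log2 change 6.91 ± 0.22 SE, limma adjusted p = 7.76e-13) and the chemokine CCL17 from 0.693 ± 0.295 to 156 ± 91.1. RRM2, a subunit of ribonucleotide reductase, rose from 2.54 ± 1.72 to 246 ± 35.1 and PCLAF, a PCNA-binding protein of replicating cells, from 1.55 ± 0.779 to 158 ± 3.95. KLF2 fell from 496 ± 331 to 2.22 ± 1.94 (log2 change -7.16 ± 0.44 SE, limma adjusted p = 7.33e-10) and ANXA1, annexin A1, from 1473 ± 1397 to 18.8 ± 8.77. The phosphatase gene DUSP1 fell from 367 ± 350.2 to 5.61 ± 0.706, KLF3 from 93.8 ± 16.1 to 1.71 ± 0.449 and NOG, the BMP antagonist noggin, from 56.2 ± 29.6 to 0.045 ± 0.0208. The naive mean was 922.5 for ANXA1 without donor 1 and 209.5 for DUSP1 without donor 4.

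Of the Th9 and type 2 cytokines, 7 of 8 tested members rose and 1 fell. IL5 went from 0.34 ± 0.252 to 21.2 ± 15.6, IL13 from 0.268 ± 0.141 to 26.3 ± 17.5 and AREG, amphiregulin, from 15.8 ± 2.56 to 1.26 ± 1.11. IL4, IL10 and SPI1 stayed under the filter on low values, at 0.198 ± 0.0866, 0.23 ± 0.296 and 0.045 ± 0.052 at d5. IL1RL1 was not tested either, since fewer than 4 libraries reached 1 FPKM. Its mean was 0.0075 ± 0.0096 in naive cells, 2.27 ± 1.09 at d5, 0.1825 ± 0.0881 at d8 and 0.2475 ± 0.0914 at d15. Of the innate cytokine receptors, 7 of 12 tested members rose and 2 fell, IL17RB going from 3.9 ± 2.03 to 140.1 ± 51.3 and IL7R from 559.6 ± 276 to 15.4 ± 9.39. Transcription factors of the Th9 list that rose included BATF3 from 1.7 ± 0.765 to 116 ± 57.4 and PPARG, a nuclear receptor linked to lipid uptake, from 0.31 ± 0.144 to 13.8 ± 4.69. IRF4 rose from 19.9 ± 14.7 to 116 ± 10.2, BATF from 16.9 ± 8.74 to 101 ± 25.2 and GATA3 from 21.4 ± 2.63 to 93 ± 31.6. There were 8 higher and 6 lower of 18 for the Th9 transcription factors, whose median log2 change was 0.07 as deposited and -0.23 with median-of-ratios scaling. Of the Th2 genes, 6 of 7 rose, CCR4 going from 7.64 ± 1.43 to 233 ± 29.9. Of the Th1 genes, 5 of 8 rose, the IL-12 receptor gene IL12RB2 with a log2 change of 2.32. All 22 cell cycle genes rose (MKI67 from 1.11 ± 0.456 to 57.5 ± 12.7), and 13 higher and 1 lower of 16 glycolysis genes passed (GAPDH from 419.6 ± 130.1 to 4377 ± 606). So did 14 higher and 1 lower of 15 of oxidative phosphorylation (COX5A from 54.4 ± 11.4 to 404 ± 54.5) and 11 higher and 1 lower of 18 of cholesterol synthesis (FDPS from 45.2 ± 6.61 to 309 ± 19). Amino acid stress genes were 10 higher and 1 lower of 14 (10 and 2 adjusted over the list alone), PSAT1, a serine synthesis enzyme, going from 1.68 ± 0.517 to 58.9 ± 6.88. Naive and quiescence genes fell in 16 of 17 cases, TCF7 going from 403 ± 257 to 34.3 ± 12. Interferon response genes were 1 higher and 9 lower of 14 (1 and 10 adjusted over the list alone). Limma called 5434 higher and 3100 lower of 14147 genes, or 9915 within donors 1 and 2 and 7895 within donors 3 and 4. The share higher was 63.7% as deposited (median log2 change of all genes 0.24), 49.8% with median-of-ratios scaling (-0.02) and 48.3% with quantile normalization (-0.05). The naive mean of IRF4 was 12.6 without donor 1 and the d5 mean of IL5 was 14 without donor 3.

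Human d8 against d5 covers the first 3 days without stimulation. IL9 fell from 285 ± 207 to 33.7 ± 12.5 FPKM (log2 change -2.78 ± 0.44 SE, limma adjusted p = 0.000562), IL13 from 26.3 ± 17.5 to 1.42 ± 0.659 and LTA from 387 ± 241 to 51.7 ± 19.8. Of the Th9 and type 2 cytokines, 0 of 8 tested members rose and 6 fell (0 and 7 adjusted over the list alone). Of the immediate early and TCR-induced genes, 14 of 19 (15 adjusted over the list alone) fell and 0 rose. NR4A1 fell from 33.1 ± 16.6 to 1.1 ± 0.293 and EGR2, a zinc finger factor, had a log2 change of -3.84. TNFRSF18, the costimulatory receptor GITR, fell from 93.1 ± 31.3 to 3.5 ± 1.25 (log2 change -4.37 ± 0.27 SE, limma adjusted p = 9.25e-08) and ZBED2 from 261 ± 55.4 to 13.2 ± 2.98. PDCD1 fell from 10.4 ± 2.9 to 0.752 ± 0.227 and CTLA4 from 44.5 ± 15.7 to 10.2 ± 3.53. The largest rise was that of PTGDR2, the prostaglandin D2 receptor CRTH2 of Th2 cells, from 0.958 ± 0.945 to 22.2 ± 8.48 (log2 change 3.61 ± 0.32 SE, limma adjusted p = 2.25e-06). KRT1, a keratin gene, rose from 10.8 ± 2.2 to 142 ± 39.2, PDLIM1, a cytoskeletal adaptor, from 1.73 ± 1.13 to 28.7 ± 11.7 and KLF2 from 2.22 ± 1.94 to 27 ± 6.22. SELPLG, a selectin ligand, rose from 17.7 ± 3.72 to 80.9 ± 6.83. None of the 22 cell cycle genes and none of the 16 glycolysis genes passed, and GATA3 was at 93 ± 31.6 and 96.7 ± 29.1. In all, 682 higher and 691 lower genes were called. The total of 1373 was 894 without the d8 library of donor 1, 857 without that of donor 2, 4798 within donors 1 and 2 and 505 within donors 3 and 4. The share higher was 49.7% as deposited (median log2 change of all genes 0.04) and 67.9% with TPM scaling (0.18). It was 53.7% with a pseudocount of 0.1, 50.7% with array quality weights, 50.8% in a fit of the 2 groups alone and 50.6% with the donor as a block. Without a filter on low values it was 39.1%.

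From human d8 to d15, 7 further days without stimulation, genes of the cytotoxic and homing lists were among those that rose. GZMA rose from 28.2 ± 21.5 to 359 ± 45.9 FPKM (log2 change 3.98 ± 0.56 SE, limma adjusted p = 0.000558) and GZMB from 8.04 ± 3.96 to 102 ± 35. In all, 6 of 13 (8 adjusted over the list alone) cytotoxic genes were higher and 0 lower. IGFBP2, an insulin-like growth factor binding protein, rose from 2.36 ± 3.42 to 63.7 ± 60.3. Of the chemokine receptor and homing genes, 7 of 15 rose, the chemokine receptor gene CXCR6 going from 1.83 ± 1.47 to 13.1 ± 4.38. Immediate early and TCR-induced genes, of which none rose from d5 to d8, were 5 higher and 0 lower of 19 from d8 to d15. At d15 against d5 that list had 3 higher and 9 lower (3 and 10 adjusted over the list alone). Of the Th9 and type 2 cytokines, 0 of 8 tested members rose and 3 fell (1 and 3 adjusted over the list alone). IL9 fell from 33.7 ± 12.5 to 4.96 ± 1.42 (log2 change -2.51 ± 0.44 SE, limma adjusted p = 0.00223), IL5 from 11.4 ± 4.24 to 1.17 ± 0.318 and CCL17 from 20.7 ± 10.7 to 2.26 ± 1.04. PPP1R14A, an inhibitor of myosin phosphatase, fell from 56.1 ± 13.9 to 12.4 ± 5.85 and BATF3 from 113 ± 19.2 to 41 ± 15.9. Cell cycle genes fell in 12 of 22 (14 adjusted over the list alone) cases. Glycolysis genes rose in 6 of 16 (8 adjusted over the list alone), the glucose transporter SLC2A3 going from 36.5 ± 8.28 to 108 ± 14.1. Limma called 641 higher and 693 lower genes, and 928 higher and 1159 lower with the donor as a block. That total of 1334 was 795, 808 and 818 without the d8 library of donor 1, 3 or 4, 793 without the d15 library of donor 3, 3627 within donors 1 and 2 and 553 within donors 3 and 4. The share of calls that were higher was 48.1% as reported, 53.6% with median-of-ratios scaling, 53.3% without a filter on low values, 51.5% with array quality weights and 68.6% among calls of at least 2-fold. The d15 mean of IGFBP2 was 35.1 without donor 3.

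Human d15 against d5 spans the whole time without stimulation. IL9 fell from 285 ± 207 to 4.96 ± 1.42 FPKM (log2 change -5.29 ± 0.44 SE, limma adjusted p = 4.09e-07), CCL17 from 156 ± 91.1 to 2.26 ± 1.04 and ZBED2 from 261 ± 55.4 to 5.47 ± 0.484. GNG8, a G protein γ subunit, fell from 58.9 ± 13.9 to 0.752 ± 1.06 and LTA from 387 ± 241 to 14.8 ± 3.11. Th9 and type 2 cytokines fell in 7 of 8 cases, IL5 going from 21.2 ± 15.6 to 1.17 ± 0.318. GZMA rose from 2.55 ± 2.2 to 359 ± 45.9 (log2 change 6.84 ± 0.56 SE, limma adjusted p = 3.97e-07). It lies on the plus strand of chromosome 5, from 55102648 to 55110252 of GRCh38, in GENCODE release 29. Of the cytotoxic genes, 7 of 13 tested members rose and 1 fell. EOMES, a T-box factor of cytotoxic cells, rose from 0.44 ± 0.168 to 19.1 ± 13.1. Among markers of CD8 T and NK cells, CD8A rose from 0.47 ± 0.184 to 6.65 ± 3.59 while CD8B fell from 7.44 ± 4.98 to 1.41 ± 1.41. That call ended without the d5 library of donor 1 (-1.44, limma adjusted p = 0.0512). CLU, the chaperone clusterin, rose from 0.36 ± 0.122 to 29.3 ± 8.45 and PPFIA4, a liprin, from 0.333 ± 0.258 to 31.2 ± 15.7. IGFBP2 rose from 1.11 ± 0.406 to 63.7 ± 60.3 and MIR210HG, the host transcript of the hypoxia-responsive microRNA-210, from 1.6 ± 0.958 to 54.6 ± 17.8.

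In the same comparison glycolysis genes rose in 10 of 16 cases, with the lactate exporter gene SLC16A3 going from 12.6 ± 3.06 to 129.9 ± 24.9 (log2 change 3.27 ± 0.51 SE, limma adjusted p = 0.000148). Of the chemokine receptor and homing genes, 8 of 15 (10 adjusted over the list alone) rose, SELPLG going from 17.7 ± 3.72 to 169 ± 29.4. PTGDR2 rose from 0.958 ± 0.945 to 37.6 ± 14 and LRRC32 from 0.705 ± 0.481 to 31.3 ± 10.1. KLF2 rose from 2.22 ± 1.94 to 40.2 ± 13.7 and the interferon-inducible gene RSAD2 from 1.5 ± 0.587 to 19.1 ± 5.88. Interferon response genes rose in 8 of 14 cases. Ribosome biogenesis genes fell in 14 of 16, oxidative phosphorylation genes in 11 of 15 (CYCS, cytochrome c, from 239 ± 45.4 to 73.2 ± 7.08) and cell cycle genes in 11 of 22 (14 adjusted over the list alone). IRF4 fell from 116 ± 10.2 to 31.4 ± 7.15, and GATA3, at 93 ± 31.6 and 91.5 ± 19.7, did not pass. Calls numbered 2318 higher and 2441 lower. The total of 4759 was 7284 within donors 1 and 2 and 2891 within donors 3 and 4. The share higher was 48.7% as deposited (median log2 change of all genes 0.01), 60.5% with TPM scaling (0.12), 51.9% with array quality weights and 51.8% among calls of at least 2-fold.

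**Figure D3:**
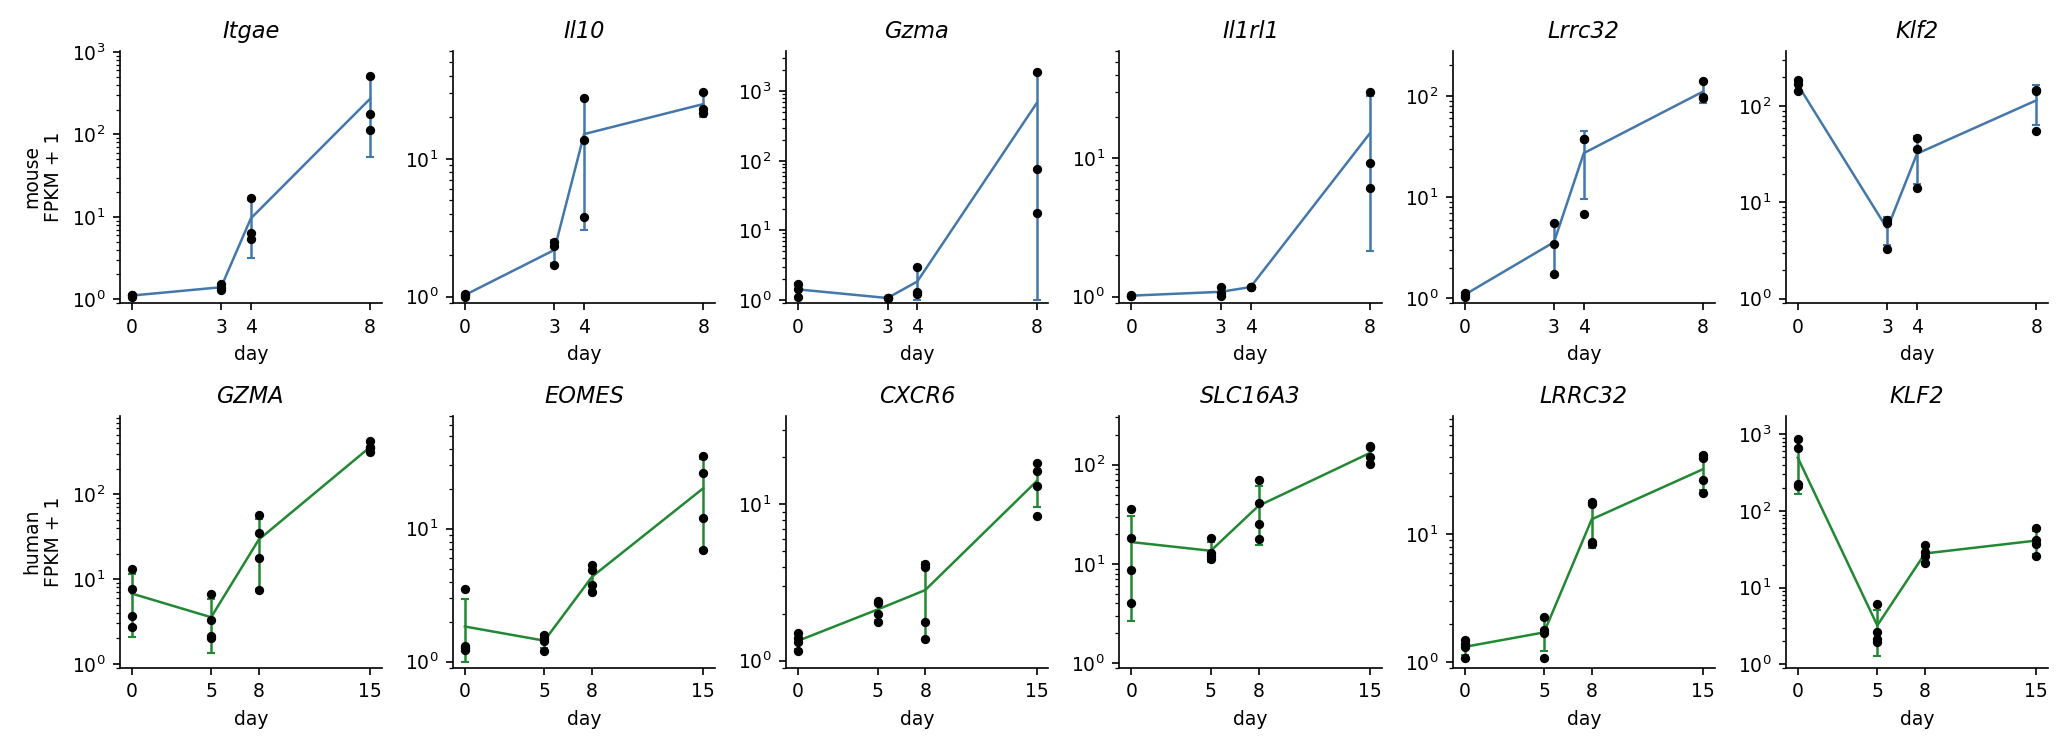
FPKM (vertical axis, log scale, with a pseudocount of 1 added) against day of culture (horizontal axis) for 6 mouse genes (top) and 6 human genes (bottom). Each gene had a higher mean at the end of culture than at the end of stimulation. There is 1 point per library, a line through the group means and bars of 1 SD that stop at 0 FPKM. Itgae went from 0.397 at mouse d3 to 269.6 at d8, and GZMA from 2.55 at human d5 to 359 at d15.

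Human d15 cells still differed widely from naive cells. RRM2 rose from 2.54 ± 1.72 to 231 ± 11.9 FPKM and GZMA from 5.77 ± 4.71 to 359 ± 45.9 (log2 change 6.00 ± 0.56 SE, limma adjusted p = 1.82e-07). IL17RB rose from 3.9 ± 2.03 to 276 ± 13.1 (log2 change 5.92 ± 0.29 SE, limma adjusted p = 7.36e-11). The MHC class II genes HLA-DRA from 8.21 ± 4.28 to 520.2 ± 109 and HLA-DRB1 from 6.33 ± 4.36 to 330.2 ± 102 rose too. The second is uncertain because near copies share its reads. Of 3 tested B cell markers, CD79B rose from 6.42 ± 4.86 to 16.5 ± 5.96 and BLK from 1.4 ± 0.728 to 3.48 ± 1.86, while CD79A fell from 2.11 ± 1.46 to 0.555 ± 0.272. IL9 remained above naive levels, from 1.01 ± 0.698 to 4.96 ± 1.42 (log2 change 1.60 ± 0.44 SE, limma adjusted p = 0.00566). All 22 cell cycle genes rose, and 15 higher and 1 lower of 16 glycolysis genes passed (GPI from 50.1 ± 20.7 to 812 ± 206). Genes of the p53 response were 8 higher and 2 lower of 13, BAX, a pro-apoptotic gene, going from 60.5 ± 35.4 to 424 ± 75.6. Treg genes were 5 higher and 1 lower of 7, FOXP3 going from 3.23 ± 1.47 to 20.9 ± 12. Th2 genes were 5 higher and 0 lower of 7, PTGDR2 going from 0.355 ± 0.19 to 37.6 ± 14. Of the naive and quiescence genes, 1 of 17 tested members rose and 15 fell, IL7R going from 559.6 ± 276 to 26.1 ± 4.95 and TCF7 from 403 ± 257 to 35.3 ± 8.26. FOS fell from 1189.6 ± 1329 to 23.5 ± 24.8 and NR4A2 from 52.7 ± 21 to 1.21 ± 0.954. The integrin gene ITGA6 fell from 60.8 ± 10.1 to 1.56 ± 0.568 and NOG from 56.2 ± 29.6 to 0.085 ± 0.0300. Between these groups limma called 5155 higher and 2421 lower genes, or 9676 within donors 1 and 2 and 6458 within donors 3 and 4. The share higher was 68% as deposited (median log2 change of all genes 0.25), 49.9% with median-of-ratios scaling (-0.03), 47.6% with quantile normalization (-0.07) and 79.6% with TPM scaling (0.49). The mean of FOS was 594 in naive cells without donor 4 and 15.4 at d15 without donor 3, and that of GZMA in naive cells was 3.67 without donor 1.

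Lists of markers of other cell types were also examined. Of 8 B cell markers, 1 was tested in mouse, Cd79b, which rose at d3 (log2 change 1.22 ± 0.16 SE, limma adjusted p = 4.09e-05) and fell at d4 and again by d8. In human 3 were tested, of which CD79B rose at d5 from 6.42 ± 4.86 to 21.8 ± 4.79. At d15, 2 were higher and 1 lower than in naive cells, and 1 was higher and 1 lower than at d5. Of 12 myeloid markers, 2 were tested in each species, with 1 higher and 1 lower at mouse d3 and at d8 against naive cells. In human, CST3, cystatin C, rose at d5 from 0.675 ± 0.257 to 2.13 ± 0.245 and was lower at d8 and d15 than at d5. Of 8 CD8 T and NK cell markers, 4 were tested in mouse, with 2 higher and 2 lower at d3, 0 higher and 2 lower at d4 and at d8 against d3, and 0 higher and 2 lower at d8 against naive cells. In human 5 were tested, with 3 higher and 0 lower at d5. At d8 1 was higher and 1 lower than at d5, and at d15 2 were higher and 2 lower than at d5, and 2 higher and 0 lower than in naive cells. Klrd1, a killer lectin receptor, fell at mouse d3 from 22.4 ± 5.39 to 0.55 ± 0.178 and Nkg7, a granule protein, rose from 0.507 ± 0.376 to 17.7 ± 11.1. Of 8 red cell and platelet markers, 0 were tested in human and 1 in mouse, with 0 calls in any comparison (1 higher at d8 against d3 adjusted over the list alone). Of 7 mast cell and basophil markers, 0 were tested in mouse and 1 in human, KIT, the stem cell factor receptor, which rose at d5 from 0.0800 ± 0.0762 to 1.23 ± 0.176 and was lower at d15 than at d5. The d3 mean of Nkg7 was 11.3 without set 1.

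Genes that rose with stimulation often fell after it. In mouse, 2716 genes rose at d3 and fell by d8, 63.9% of the 4248 that rose, against 1049 for independent lists. In human, 1992 rose at d5 and fell by d15, 36.7% of 5434, against 938 for independent lists. Il9, Irf4, Il2ra and Mki67 were among them in mouse and IL9, IRF4, IL2RA and IL13 in human. Both comparisons of a species share the libraries at the end of stimulation. With those libraries divided between the 2 comparisons, the count lay between 1788 and 2213 over 6 splits in mouse, against 690 to 867 for independent lists of the same sizes. In human it lay between 1185 and 1506 over 6 splits, against 494 to 759. Both divided fits still share the libraries of the other groups, and so much of each gene's spread. The counts for independent lists can therefore be too low a reference.

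Mouse and human cells were compared by gene symbol over 9116 genes tested in both, without a p-value, since the tables were made separately and species, times and cytokines differ together. At the end of stimulation 2290 genes were called higher in both species (1454 for independent lists), 1040 lower in both (563) and 784 in opposite directions (1898), with a Spearman rho of 0.51 across genes. Genes are not independent replicates. At the end of culture against the end of stimulation, 950 were higher in both (514), 1093 lower in both (493) and 310 in opposite directions (1035), with a rho of 0.51. With TPM scaling 1291 were higher in both and 693 lower in both, so which of the 2 counts is larger depends on the scaling. Il9 and IL9, Lta and LTA, and Irf4 and IRF4 fell in both species in this second comparison, and Gzma and GZMA, Lrrc32 and LRRC32, and Klf2 and KLF2 rose. Itgae rose from 0.397 ± 0.106 to 269.6 ± 217 in mouse, whereas ITGAE fell from 105 ± 13.8 to 57.6 ± 11.8 in human. Slc16a3 fell from 169.9 ± 46.5 to 16.7 ± 2.15 in mouse, whereas SLC16A3 rose from 12.6 ± 3.06 to 129.9 ± 24.9 in human.

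**Figure D4:**
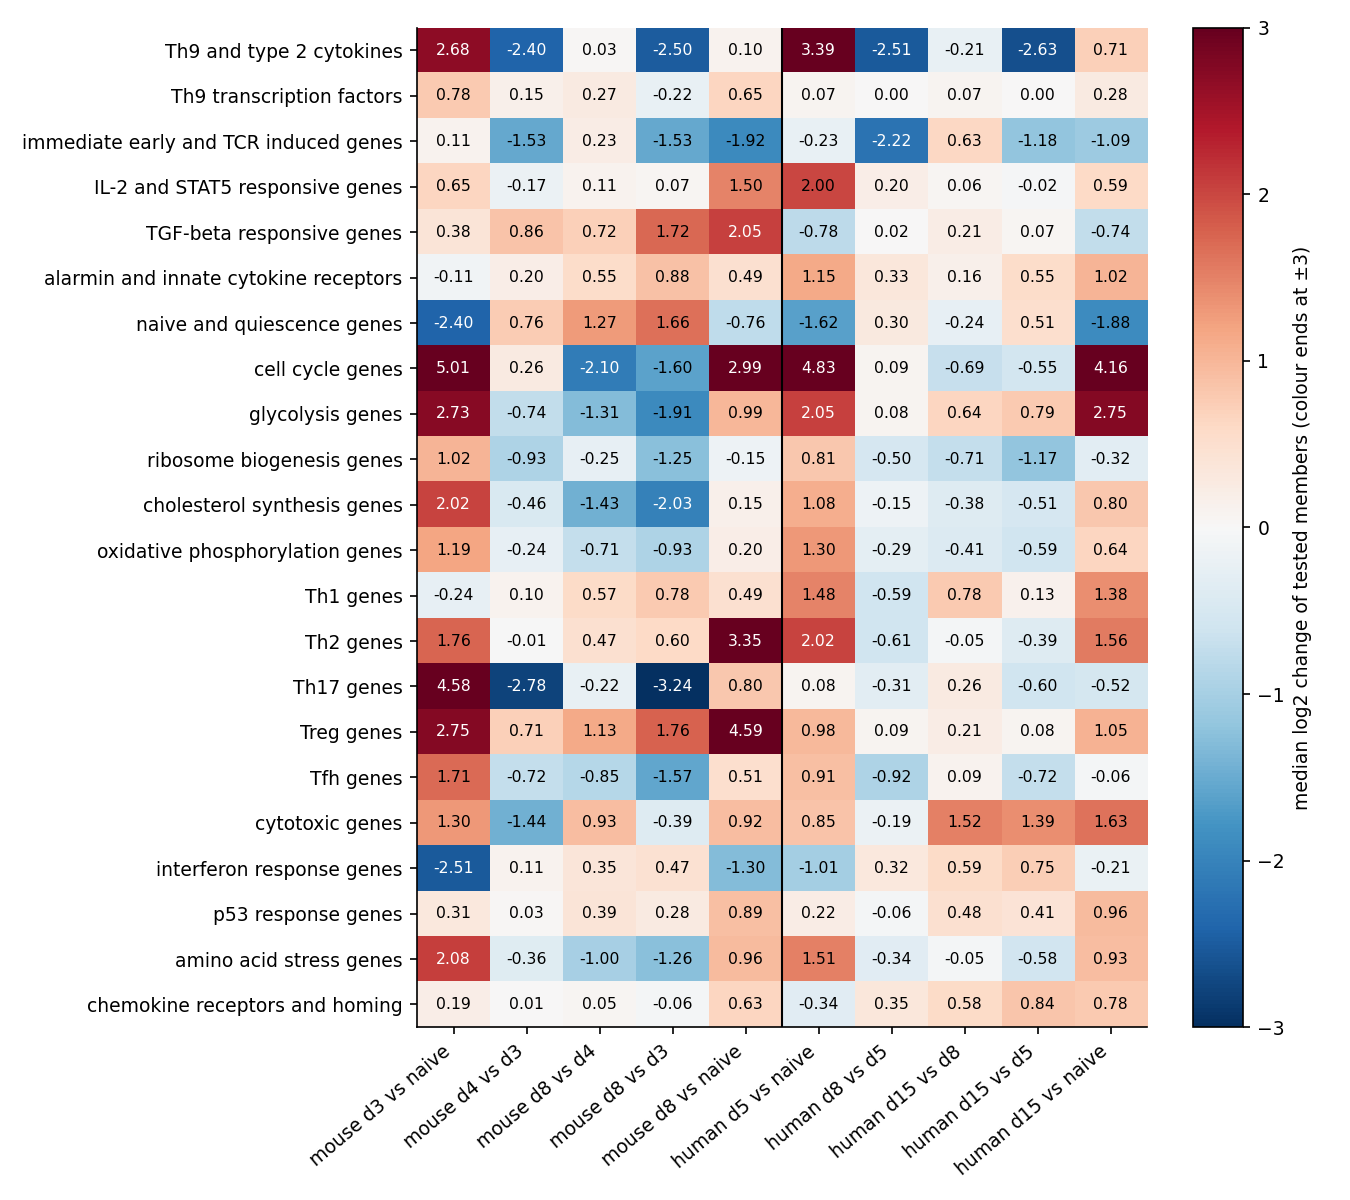
Median log2 change of the tested members of 22 gene lists (listed downwards) in the 10 comparisons (across, mouse left and human right), as a colour from blue (lower) through white (0) to red (higher), with the number in each cell. Cell cycle genes had medians of 5.01 at mouse d3 and 4.83 at human d5 against naive cells, and glycolysis genes had medians of -1.91 at mouse d8 against d3 and 0.79 at human d15 against d5.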

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

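The tests of CD8 T cell outgrowth, NK cell outgrowth, both scaling explanations and cycling cells were chosen only after the result was seen.

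Single human libraries stood apart from the other 3 of their group in 8 of 195 groups of 4 values tested (171 gene levels given in the report and 24 library measures), by a gap that chance exceeds in about 1 group in 20. High libraries were donor 4 for BATF3 at d15 (64.5 FPKM against 30.6 to 36.3 in the others), for GAPDH in naive cells (613 against 339.8 to 382), for IL12RB2 in naive cells (0.81 against 0.25 to 0.34) and for ZBED2 at d5 (344 against 228 to 236). Donor 3 was high for IGFBP2 at d8 (7.48 against 0.41 to 0.84) and IL10 at d5 (0.67 against 0.03 to 0.11). Low libraries were donor 1 for IRF4 at d5 (100.5 against 118 to 122) and donor 4 for MIR210HG at d15 (28.2 against 59.5 to 65.9). At this rate of flags none was followed further.

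ITGAE and SLC16A3 moved in opposite directions in the 2 species between the end of stimulation and the end of culture, with no overlap between the libraries of either species. ITGAE had a log2 change of -0.87 in human and Itgae one of 7.30 in mouse. SLC16A3 had a log2 change of 3.27 in human and Slc16a3 one of -3.24 in mouse. The difference between the species was not tested, and species, protocol and times differ together.

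Genes of the cytotoxic list were more often higher than lower in human d15 against d5 cultures (7 higher and 1 lower of 13). The list holds surface receptors as well as granule genes. Outgrowth of CD8 T cells would raise both chains of CD8. CD8A did rise, from 0.47 to 6.65 FPKM, while CD8B fell with a log2 change of -1.77 (7.44 to 1.41 FPKM). Without the d5 library of donor 1 the change of CD8B was -1.44 and no longer called. At d5 CD8B was at 7.44 FPKM with CD8A at 0.47, so it need not mark cells with both chains. Its fall therefore cannot decide the question. The scaling of the tables is argued against, since the median log2 change of the cytotoxic genes stayed at or above 1.37 under 3 other scalings. Outgrowth of NK cells is argued against as well, since it would raise their markers along with the cytotoxic list (median log2 change 1.39). The 5 markers taken had a median of -0.072 (SD 0.227). Their means at d5 and d15 were 1.12 and 0.575 FPKM for KLRD1, 0.498 and 0.248 for FCER1G, and 0.278 and 0.205 for NCR1. Those of KLRF1 were 0.128 and 0.21 and those of TYROBP 0 and 0.025, against 359 for GZMA at d15. Outgrowth of CD8 T cells and a cytotoxic program within the CD4 T cells remain open, and no group of the design tells them apart. Outgrowth of other cytotoxic cells from the naive preparations was not tested. GZMA was at 5.77 FPKM on average in naive cells, and at 3.67 without donor 1.

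Glycolysis genes were higher in human d15 than in d5 cultures and lower in mouse d8 than in d3 cultures. Scaling is argued against, as the human median log2 change was at least 0.77 under 3 other scalings, and so is a larger share of cycling cells, as the median of the cell cycle genes was -0.55. Low oxygen in dense human cultures remains open: oxygen-regulated genes outside glycolysis, a list prompted by MIR210HG and PPFIA4 and written before the values of its genes were examined, had a median log2 change of 1.76 in human, with 14 of 16 called higher and 1 lower, and of -1.04 in mouse. Neither oxygen nor cell density was measured, and species is confounded with time and protocol. Low oxygen may thus be part of the human pattern, but a metabolic program of late human T cells without low oxygen was not tested.

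Mouse sets differed in Il9 at d4 and in cell cycle genes and Gzma at d8. A swap between groups is argued against, since 0 mouse libraries correlated better with another group than with their own. Sets at different stages of the same path remain open. Positions on the path from d3 to d8 were measured without Il9, Gzma and the cell cycle genes. The genes and end points for each set came from the other sets, so positions do not share 1 axis and gaps between sets are approximate. The d4 library of set 2, with the least Il9, lay farthest along, 0.088 beyond the next one (0.562 against 0.474 and 0.291). The d3 libraries had an SD of 0.0233. At d8 the library of set 1 lay 0.117 behind the next one (0.855 against 0.972 and 1.01). Its Mki67 of 53.5 FPKM at d8, against 24.1 and 21.5, may go with this. From d3 to d4, however, Mki67 went from 110 to 77.1 in set 1, from 84.7 to 179 in set 2 and from 73.2 to 186 in set 3. Whether a delay gives the course of set 1 was not tested. A delay alone does not account for its Il9 of 0.31, the lowest at d8, or its Gzma of 1911, and whether the sets differ in animals, cultures or handling was not tested.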

How the results depend on the processing

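Only leaving out mouse set 1 and using 1 pair of donors were chosen after the result was seen.

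All 14 counts (10 totals of calls, 2 of genes that rose and then fell, 2 of calls in the same direction in both species) stayed within 1.5 times their reported value with a pseudocount of 0.1, without a filter on low values, with TPM, median-of-ratios or quantile scaling, and without a variance trend. Parts in 1 direction moved further. With TPM scaling these were mouse d4 against d3 (2624 higher and 575 lower), human d15 against naive (1607 lower) and genes lower in both species at the end of culture (693). Human d15 against naive also had 3819 lower with median-of-ratios and 4083 with quantile scaling, and mouse d8 against naive 2306 lower with quantile scaling. With a change of at least 2-fold required, a rule that can only shorten the lists, mouse comparisons in the order of the report kept 5294, 1047, 1895, 4154 and 2221 calls and human ones 5417, 614, 475, 2077 and 4431. It left 1465 genes that rose and then fell in mouse and 748 in human, and 1725 and 691 calls in the same direction in both species, at the end of stimulation and of culture.

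Array quality weights gave 6212 calls for mouse d4 against d3, 8465 for d8 against d4 and 8392 for d8 against naive, and in human 4807 for d8 against d5, 4988 for d15 against d8 and 8096 for d15 against d5. Calls in the same direction in both species at the end of culture became 3788, and the cause was not tested. A fit on only the 2 groups compared, which pools the spread over fewer libraries, gave 970 for mouse d4 against d3, and 2170 and 2560 for human d8 against d5 and d15 against d8. The main human fit ignores the donor, although the same donors recur in every group. With the donor as a block, human totals in the order of the report were 9241, 1866, 2087, 5649 and 8288, each above the main total. The main mouse fit likewise ignores the set, although the set numbers recur in every group. With the set as a block, mouse totals were 8559, 2785, 4963, 7809 and 4570, each above the main total. Without set 1, mouse d4 against d3 gave 4861, and the cause was not tested.

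Donors 1 and 2 alone gave 4798, 3627 and 7284 calls for human d8 against d5, d15 against d8 and d15 against d5, and 3088 calls in the same direction in both species at the end of culture. Donors 3 and 4 alone gave 505, 553 and 2891, with 1180 human genes that rose and then fell and 1248 calls in the same direction at the end of culture. Mitochondrial genes held 15.9% and 15.0% of summed FPKM at d5 in donors 1 and 2, against 9.15% and 10.7% in donors 3 and 4. At d15 these shares were 6.51% and 6.42%, against 5.72% and 6.29%. The cause of the difference between the pairs was not tested.

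Leaving out 1 library at a time gave 7533 to 8210 calls for mouse d3 against naive, 1375 to 3464 for d4 against d3, 2973 to 5190 for d8 against d4, 6456 to 7779 for d8 against d3 and 3189 to 3889 for d8 against naive. In human it gave 7908 to 8684, 857 to 1401, 793 to 1151, 3924 to 4881 and 6972 to 8042. Genes that rose and then fell numbered 2321 to 2785 in mouse and 1632 to 2099 in human, and calls in the same direction 3053 to 3322 at the end of stimulation and 1708 to 2049 at the end of culture.

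Genes picked by the 3 naming rules, taken per comparison, also lost calls. Without a filter on low values 54 lost their call and 688 had the same result, and with TPM scaling 25 and 713. A fit of the 2 groups alone gave 41 and 696, the set or donor as a block 5 and 734, and donors 3 and 4 alone 74 and 286. Changes of sign were seen only for core genes that had not been called. With scaling these were Il1rl1 at mouse d3 against naive (-0.074 with quantile normalization), Ccr7 at d8 against d4 (-0.050 with median-of-ratios), and in human CISH at d15 against d8 (-0.0061 with TPM), CCR7 at d15 against d5 (0.051 with TPM and 0.051 with quantile normalization) and GATA3 at d15 against d5 (-0.013 with median-of-ratios). Array quality weights gave Ccr7 0.32 and 0.56 at mouse d4 and d8 against d3 and CCR7 0.46 at human d15 against d5. Without set 1, Ccr7 had 0.12 and 0.21 in those mouse comparisons and Batf -0.017 at d4 against d3. Donors 1 and 2 alone gave CCR7 0.091 at d15 against d8 and 0.63 against d5. Donors 3 and 4 alone gave GATA3 -0.62 and TCF7 -0.21 at d8 against d5, IL13 0.017, GATA3 0.59 and CISH -0.56 at d15 against d8, and GATA3 -0.027, CISH -0.036, TCF7 -0.50 and MKI67 -0.25 at d15 against d5.

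With 1 library left out, log2 changes ran from -0.11 to 0.46 for Batf and from -0.010 to 0.48 for Cish at mouse d4 against d3, and from -0.049 to 0.88 for Il4 at d8 against d3. Those of Ccr7 ran from -0.91 to 0.20 (d3 against naive), from -0.96 to 0.15 (d4 against d3), from -0.038 to 0.10 (d8 against d4) and from -0.91 to 0.19 (d8 against d3). In human they ran from -0.076 to 0.27 for GATA3 at d8 against d5, from -0.23 to 0.082 for GATA3 and from -0.27 to 0.35 for CISH at d15 against d8, and at d15 against d5 from -0.11 to 0.22 for GATA3, from -0.27 to 0.19 for CCR7 and from -0.15 to 0.24 for TCF7. The cause of these changes of sign was not tested, and each started from a change near 0 or a spread as large as the change.

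Depth generally limits genes of low level most, but its effect on these data was not tested. Il5 in mouse and IL4, IL10 and IL1RL1 in human, at or below 2.78 FPKM on average in every group, were left untested by the filter.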

Other observations

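The splits of libraries were planned, while the comparison of donor pairs was chosen only after the result was seen.

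Human counts of calls were set against the 35 splits of the same libraries into groups of 4. In each comparison only 1 split, the real grouping, gave as many. Every other split, in either species, mixes the 2 groups, so real differences enter its spread and hold its count down. Counts of the other splits are therefore no chance level for the real ones. Real and highest other counts were 8534 and 17 for d5 against naive, 1373 and 1 for d8 against d5, 1334 and 2 for d15 against d8, 4759 and 1287 for d15 against d5, and 7576 and 2 for d15 against naive. The 1287 came from the split of donors 1 and 2 against donors 3 and 4, so these pairs differ in a structure of their own at d5 and d15. The same donors recur in both groups, so the closest match to the real grouping are the 8 splits that part the 2 libraries of every donor, while the others put both libraries of some donors in 1 group. The highest other counts among these 8 were 0, 1, 0, 0 and 1 in the order above, and 8 splits are too few to test. With the donor as a block the real count of d15 against d5 was 5649. Mouse comparisons have 10 splits each, too few to test, and 1 of them, the real grouping, gave the highest count in each, with real and highest other counts of 8350 and 3, 2593 and 0, 4690 and 2, 7610 and 5, and 4334 and 1 in the order of the report.

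Changes from naive cells to the end of culture correlated less between mouse and human (Spearman rho 0.27 across genes) than those at the end of stimulation (0.51). Calls were also fewer, 4334 against 8350 in mouse and 7576 against 8534 in human, and smaller changes alone can lower a rank correlation. The ends of culture lay 5 and 10 days past stimulation. In naive human cells, donor 1 had NKG7 at 52.5 FPKM and GNLY at 105, levels from which the later groups are measured.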
